A study of Drosophila melanogaster with 2 samples.

How the data were processed

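Binding of CG13287, a Drosophila melanogaster protein, was measured by chromatin immunoprecipitation and sequencing in whole embryos aged 6 to 24 h that carried a CG13287-eGFP fusion transgene. The fusion protein was recovered with an antibody against GFP, and chromatin was fragmented by sonication to 200 to 800 bp, per the labels. The series held 2 biological replicates of 1 group, and no other genotype, stage or treatment. Replicates carry the numbers given in the labels. The ages were read from the sample description, because the separate age field held a number that cannot be an age in hours.

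The deposited data were peak lists on the dm6 assembly, with no read counts, so the depth of each library is unknown. There were 4 lists filtered by the irreproducible discovery rate (IDR) and 4 longer ranked lists that preceded the filter. Each replicate had 1 list of each kind. The 2 replicates together had a conservative and an optimal filtered list and 2 ranked lists. Per the labels of the deposited listing, all lists derive from filtered alignments of the replicate or replicates concerned, and the filtered lists also from a further file whose content was not stated. The aligner, the peak caller and the scaling against a control are not given in the sources used here. The deposited signal is the peak signal value as the peak caller gave it, and how it relates to depth and control was not stated. The deposited score is the scaled IDR score, capped at 1000. In the ranked lists a further deposited score is minus log10 of the global IDR, from which the scaled score followed within 1 unit in 100.0% of the peaks. The lowest score in each filtered list was 830, which is an IDR of 0.01. The score alone does not give the filtered lists, because 6148 peaks of the conservative ranked list reached 830 and 5955 were kept. Summits were taken as the peak start plus the deposited offset. In the conservative list 5 summits lay outside their interval and were kept.

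The conservative list of both replicates was the main set. Positions were read against the Ensembl BDGP6.54 annotation, without transposable elements, and the Release 6 genome sequence. The arms 2L, 2R, 3L, 3R, 4, X and Y were used, and mitochondrial peaks were left out of all comparisons. A summit was assigned to the first class it met of promoter (within 500 bp of an annotated transcription start site, TSS), 5' untranslated region, coding sequence, 3' untranslated region, other exon, intron and intergenic. A gene was counted as bound when a summit lay within 500 bp of one of its TSSs. There were 13968 protein-coding genes on the arms. The 14 gene lists written symbol by symbol matched in full, 12 of their symbols through a table from older to reference names made after the lists had been fixed. The other 7 lists were defined by a symbol pattern or biotype.

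Shares of summits per class and arm were tested with exact two-sided binomial tests against shares of bases. The 21 gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, or against genes of any biotype for tRNA and snRNA genes. Known motifs, 28 in number, and all canonical 6-mers were counted on either strand in the 101 bp around each summit and in a window of the same width 500 bp away, on a side drawn at random with seed 7. These pairs were compared with exact two-sided McNemar tests. The overlap of the replicates was set against 1000 random placements on the same arm with a one-sided test, whose smallest possible p is 0.001. Median log2 signal was compared with two-sided permutation tests of 100000 resamples, whose smallest possible p is 1e-05. Smaller p values of exact tests were floored at 1e-300. Benjamini-Hochberg adjustment was made within each family, with a threshold of 0.05. Confidence intervals are exact Clopper-Pearson 95% intervals, except that of the rank correlation, which came from 500 bootstrap draws over peaks. With 2 libraries in 1 group, every test ran over peaks, windows or genes and none over replicates. Each p therefore describes the lists, and intervals cover counting error only.

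The named items followed a rule. It took CG13287, the 20 peaks with the highest signal that overlapped a filtered peak of both replicates, and up to 4 bound members of each gene list past the threshold or 2 of each other list, by signal. It also took the 5 known motifs and 10 6-mers with the smallest p. The gene lists, motifs, classes, tests, this rule and a set of other settings were fixed before the data were examined. These other settings were the optimal list, the more intense peaks of each list (those above its median signal), each replicate's own list, promoter distances of 1000 and 200 bp, and gene bodies with 1000 bp on either side. Others were control windows 1000 bp away, windows of 25 bp on either side of the summit, and pairs of windows within 5 percentage points of GC content. For overlap they were an overlap of at least 0.5 of the shorter peak, summits within 100 bp, equal numbers of peaks, and placement that kept the promoter share. Added after the data had been seen were 1 summit per group of overlapping peaks, canonical TSSs only, and windows at the promoters of 3199 unbound genes. The comparisons of summit position, of groups by signal and of head-to-head genes were also added then.

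Each test was tried on simulated data. With nothing planted, 0 6-mers and 0 of 28 motifs were called, and all 20 planted 6-mers and all 28 motifs were recovered when planted in 5% of windows. These windows lay at random positions, so the simulation does not cover calls that arise from position at promoters. Any class was called in 9 of 200 uniform draws, as was any arm. Of 200 random gene lists 0 were called, and 198 of 200 lists of 50 genes bound at 75% against 40% were recovered. A permutation test called 8 of 200 sets without a difference. A simulated log2 difference of 0.5 was recovered as 0.57, a promoter share of 60% as 60.0%, and 50% of copied peaks as an overlap of 51.8%. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.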

Results

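The tagged CG13287 protein occupied 5955 peaks of the conservative list made from both replicates, with a median width of 514 bp and a median signal of 178. Replicate 1 alone gave 4014 filtered peaks (3997 on the chromosome arms, median signal 106) and replicate 2 gave 7340 (median signal 99.8), a ratio of 1.84 on the arms. Signals of the list from both replicates may not share a scale with those of single replicates, as mtSSB had 3000 against 1503 and 1489. The median signals are therefore not compared, also because the lists differ in length. The optimal list held 7031 peaks. Some intervals overlapped, and the conservative list formed 5168 separate groups of peaks. The depth of the libraries is unknown, and no control sample or other condition was available for comparison.

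CG13287 itself (FBgn0035643, 3L, 5882304-5884090, plus strand) had no peak within 5000 bp in any of the 4 filtered lists. This locus was examined first because the transgene adds a copy of the gene region. The ranked lists held weak entries there, 4 in replicate 1 and 5 in replicate 2. Near the start of the gene, the ranked lists of both replicates together had a peak at 5881817-5882366 with a signal of 52.97. The nearest entries of the single replicates had signals of 30.6 and 29.97, which may be on another scale than that of both replicates together.

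The 20 strongest peaks shared by both replicates all lay at promoters. The highest signal, 3000, was at mtSSB, which encodes the mitochondrial single-stranded DNA-binding protein (3R, 16204991-16205646), with 1503 in replicate 1 and 1489 in replicate 2. RhoGAP93B followed with 2758 (3R, 21097618-21098236), Rpn6, a subunit of the proteasome lid, with 2618 (2R, 14752019-14752737), and Creld with 2497 (2L, 102071-102651). CG4502 had 2163, Jwa 2102, the cell adhesion gene Nrg 1989, the ribosomal protein gene RpL32 1987 and the proteasome gene Prosalpha7 1948. Next came Sry-beta, PGAP3, Pym, the ubiquitin ligase gene Ube3a, CG11857, CG2924, CG13096, Dpit47, Gp150, CG8613 and the adducin gene hts, with signals of 1929 to 1680. All 20 summits lay upstream of the nearest TSS, at 12 to 144 bp. Of these 20 promoters 8 had TSSs of at least 2 genes within 500 bp, so the nearest gene is 1 of several candidates at Rpn6 and RpL32, for example.

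The replicates were compared to ask how far they found the same regions. Nearly all regions of replicate 1 recurred in replicate 2, since 3843 of 3997 peaks (96.1%) overlapped one there, against 4.43% on average and at most 5.78% in random placements. Of the replicate 2 peaks 3816 of 7340 (52.0%) had a partner in replicate 1, against an average of 2.19% at random. Placements that kept the share of promoter summits gave 25.4% on average (at most 27.6%) for replicate 1 and 14.6% (at most 15.9%) for replicate 2. With equal numbers of peaks in both lists the shares were 85.5% for replicate 1 and 77.1% for replicate 2. All 6 p values were 0.001, the smallest that 1000 placements can give. Among the 1000 strongest replicate 2 peaks 99.8% had a partner, among those ranked 3001 to 4000 43.0% did, among those ranked 6001 to 7000 14.1% did, and among the last, from 7001 to 7340, 41.8% did. Across 3371 shared pairs of peaks the signals of the replicates had a Spearman correlation of 0.904 (95% interval 0.896 to 0.911), given without p because peaks are not independent replicates.

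**Figure D1:**
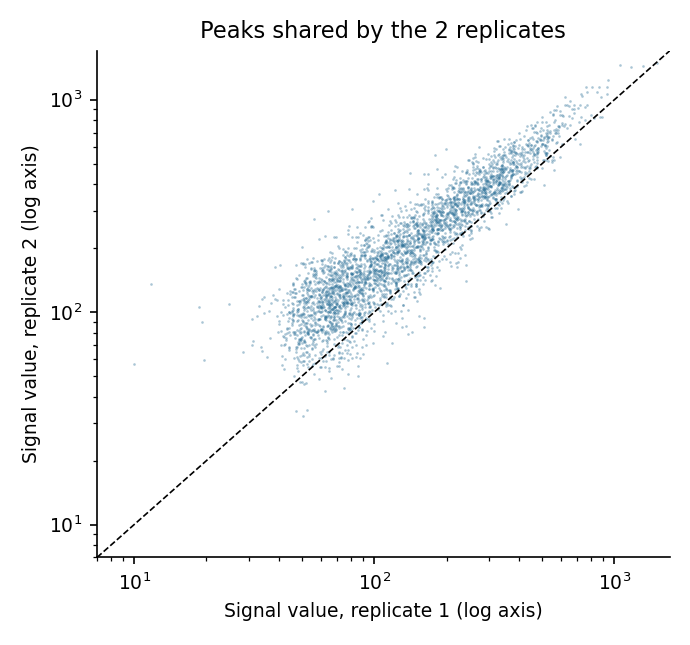
Signal value of each shared peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), 1 point per pair, with the line of equal values dashed. The 3371 pairs follow a rising band (Spearman correlation 0.904), mostly above the dashed line.

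Where in the genome the protein was found was asked of the summit positions. Promoters held 5159 of 5955 summits (86.6%, 95% interval 85.7 to 87.5), against 13.3% of bases, a 6.53-fold excess. The excess depends on the promoter width, at 13.1-fold within 200 bp and 3.91-fold within 1000 bp. Replicate 1 gave 91.0% and replicate 2 81.0%. Introns held 440 summits (7.39% against 39.1% of bases), intergenic sequence 265 (4.45% against 28.3%) and coding sequence 26 (0.437% against 13.4%, 0.0326-fold). The 3' untranslated regions held 35 summits (0.136-fold), other exons 12 (0.246-fold) and 5' untranslated regions outside promoters 18 (0.399-fold). All 7 classes passed the exact binomial test. Each summit lies in a single class, so the promoter excess by itself lowers the other classes. Their deficits against all bases are therefore not separate evidence of avoidance. Summits outside promoters were not tested against the bases outside promoters. Among the classes outside promoters, coding sequence had the lowest fold. The adjusted p was at its floor of 1e-300 for promoter, coding, intron and intergenic sequence and 6.51e-06 for 5' untranslated regions. In the lists of replicate 1 and replicate 2 the folds were 0.231 and 0.665 for 5' untranslated regions, 0.110 and 0.209 for 3' untranslated regions, 0.213 and 0.382 for other exons and 0.0187 and 0.0275 for coding sequence, all past the threshold. Among the 2977 peaks with the highest signal coding sequence was at 0.00752-fold, introns at 0.0850-fold, other exons at 0.123-fold, 3' untranslated regions at 0.0857-fold and 5' untranslated regions at 0.177-fold. With promoters drawn at 200 bp the 5' untranslated regions no longer passed the threshold (0.963-fold, exact adjusted p = 0.788).

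At promoters the summits sat just upstream of the start site. The median position was -35 bp (quartiles -88 and 15 bp), 68.5% were upstream, and 90.9% lay within 200 bp of the TSS. Promoter peaks were also stronger, with a median signal of 192 over 5159 peaks against 131 over 796 other peaks. The difference was 0.55 in log2 (two-sided permutation p = 1e-05, the smallest possible).

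**Figure D2:**
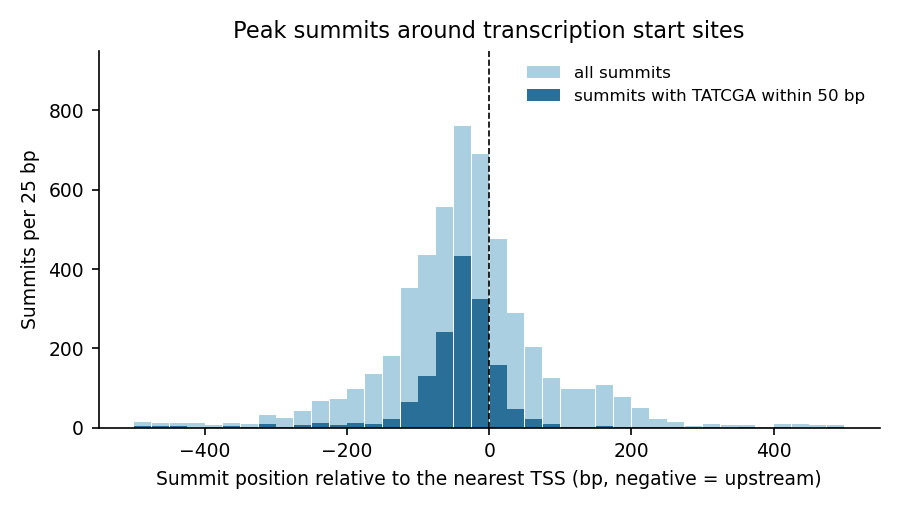
Number of summits per 25 bp (y axis) by position relative to the nearest TSS in bp (x axis, negative values upstream), for all summits (light bars) and for those with TATCGA within 50 bp (dark bars, part of the light ones). The median of the 5159 promoter summits was -35 bp.

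Among the chromosome arms, 2R carried more summits than its length would give and chromosome 4 fewer. The 1277 summits on 2R were 21.4% against 18.4% of bases (1.17-fold, exact adjusted p = 7.97e-09). However, 2R holds 20.42% of protein-coding genes, just inside the 95% interval of its summit share (20.41 to 22.51%). The test against bases thus does not show an excess over genes. Chromosome 4, which is largely heterochromatic, had 19 summits (0.326-fold, exact adjusted p = 7.97e-09) and holds 0.573% of protein-coding genes. The replicate 2 list had 50 summits there (0.695-fold, exact adjusted p = 0.0177) and that of replicate 1 had 12 (0.306-fold). The Y had 0 of 5955 summits, which allows a share of up to 0.0504% at 3 counts and 0.0619% by the exact 95% limit, against 2.67% of bases (exact adjusted p = 1.85e-69). The Y holds 0.165% of protein-coding genes, so the test against bases overstates its deficit, since most summits lay at promoters. How much of the Y can be uniquely mapped was not tested. The arms 2L, 3L, 3R and X lay between 0.990-fold and 1.02-fold of their share of bases, with adjusted p of 0.792 to 0.987. Shares of genes were not tested. Beside them X was higher (17.4%, 95% interval 16.4 to 18.3, against 15.7% of protein-coding genes). By the same measure 2L (17.4%, 16.4 to 18.3, against 19.0%) and 3R (23.1%, 22.0 to 24.2, against 24.5%) were lower. For 3L (20.4%, 19.4 to 21.5) the interval held the gene share of 19.6%. On 3L the replicate 1 list alone gave 0.932-fold (exact adjusted p = 0.0491).

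Promoters of 5565 of 13968 protein-coding genes (39.8%) were bound, 4239 in the replicate 1 list and 6266 in that of replicate 2. Gene lists asked which functions these genes have, with exact 95% intervals for the share bound. The background held all genes, whether or not they are expressed in these embryos, and no expression data were used. The lists therefore cannot tell binding by gene function from binding at active promoters of any kind. Cell cycle and DNA replication genes were bound in 35 of 44 cases (79.5%, interval 64.7 to 90.2, odds ratio 5.90, exact adjusted p = 3.84e-07), with 63.6% in replicate 1 and 81.8% in replicate 2. Their strongest members were the mitotic kinase gene aurA (signal 1029), the cyclin gene CycB (896), the replicative helicase gene Mcm5 (876) and the spindle checkpoint gene BubR1 (849). Genes of the Hedgehog, Wingless, Dpp, Egfr and Jak-Stat pathways were bound in 37 of 47 cases (78.7%, interval 64.3 to 89.3, odds ratio 5.62, exact adjusted p = 3.84e-07). The cytokine receptor gene dome had 647, the Hedgehog transducer smo 632, the transcription factor gene Stat92E 571 and the Janus kinase gene hop 529. In replicate 1 this list was bound at 55.3% (odds ratio 2.85) and in replicate 2 at 83.0% (6.02). Among the 2977 peaks with the highest signal this list fell short of the threshold (40.4% bound against 26.4% of other genes, odds ratio 1.89, exact adjusted p = 0.0945).

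Genes for insulator and promoter factors were bound in 17 of 22 cases (77.3%, interval 54.6 to 92.2, odds ratio 5.15, exact adjusted p = 0.00144). The insulator protein genes pita (887), CTCF (783), mod(mdg4) (576) and dwg (567) were the strongest. Polycomb and trithorax genes were bound in 25 of 34 cases (73.5%, interval 55.6 to 87.1, odds ratio 4.21, exact adjusted p = 3.45e-04), led by the chromatin remodelling genes kis (1041) and Iswi (957), then Scm (943) and kto (932). Cytosolic ribosomal protein genes were bound in 58 of 88 cases (65.9%, interval 55.0 to 75.7, odds ratio 2.94, exact adjusted p = 3.20e-06), with RpL32 at 1987, RpS2 at 1404, RpS30 at 1034 and RpS7 at 1007. In replicate 1 they were bound at 56.8% (odds ratio 3.04) and in replicate 2 at 80.7% (5.18). Oxidative phosphorylation genes were bound in 48 of 78 cases (61.5%, interval 49.8 to 72.3, odds ratio 2.43, exact adjusted p = 3.36e-04), with UQCR-14 at 1140, COX7B at 1059, ATPsynF at 963 and COX7A at 905. For this list too the threshold was missed among the 2977 peaks with the highest signal (37.2% bound against 26.4% of other genes, odds ratio 1.65, exact adjusted p = 0.0906).

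Of the 21 lists 4 were bound less often than other genes. Chemoreceptor genes of adult sense organs were bound in 6 of 179 cases (3.35%, interval 1.24 to 7.15, odds ratio 0.0513, exact adjusted p = 1.68e-29), among them Ir31a (549), Ir60e (303), Ir76a (186) and Gr97a (177). With promoters of 200 bp 1 was bound (0.559%, odds ratio 0.0102) and with 1000 bp 9 were (5.03%, odds ratio 0.0696), both past the threshold. Genes listed as male reproductive were bound in 4 of 72 cases (5.56%, interval 1.53 to 13.6, odds ratio 0.0882, exact adjusted p = 2.48e-10), namely Sfp24F (328), Sfp26Ad (231), Ssl1 (149) and Mst36Fa (98.6). This list was taken by symbol pattern alone, which also admits genes with other functions, such as Ssl1. With promoters of 200 bp 2 of the 72 were bound (2.78%, odds ratio 0.0526), still past the threshold. Neuronal function genes were bound in 2 of 25 cases (interval 0.984 to 26.0%, odds ratio 0.131, exact adjusted p = 0.00149), namely the active zone gene brp (158) and the receptor gene mAChR-A (32.7). Counted over gene bodies they reached 28.0% bound against 48.3% of other genes and missed the threshold (exact adjusted p = 0.0884), and the replicate 1 list alone held 0.00% against 16.0% for replicate 2. Replication-dependent histone genes were bound in 0 of 111 cases (upper 95% limit 3.27%, exact adjusted p = 4.72e-24). These genes lie in a repeated cluster, and whether reads map there was not tested. As copies within 1 cluster they are not independent genes, so the p and the upper limit overstate the evidence.

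The other 11 lists did not pass the threshold, with adjusted p of 0.0747 to 1.00. Heat shock genes were bound in 12 of 23 cases (DnaJ-1 1043, Hsp83 787), Notch pathway genes in 13 of 27 (mib1 742, mam 624) and ecdysone genes in 12 of 26 (crol 760, ftz-f1 747). For epidermis and trachea the count was 11 of 24 (shg 634, tal-1A 295), for endoderm, gut and fat body 8 of 18 (lin 240, cnc 197) and for muscle 13 of 32 (mys 949, Mef2 545). For the Hox genes it was 3 of 8 (abd-A 177, Ubx 169), for segmentation 10 of 27 (nanos 1378, bcd 347) and for neurogenesis 10 of 35 (brat 734, scrt 222). Small nuclear RNA genes gave 5 of 32 (snRNA:7SKa 277, snRNA:U1:95Ca 266). Transfer RNA genes gave 104 of 290 (35.9% against 32.5% of other genes, exact adjusted p = 0.373), with tRNA:Gly-TCC-1-2 at 873 and tRNA:Gly-GCC-1-9 at 691. In the single-replicate peak lists tRNA genes passed the threshold in opposite directions, with 18.97% bound in replicate 1 (exact adjusted p = 0.0446, less often) and 52.1% in replicate 2 (exact adjusted p = 7.54e-07, more often). Shares in replicate 1 and replicate 2 also lay far apart, without passing the threshold, for endoderm, gut and fat body (16.7% and 72.2%), epidermis and trachea (33.3% and 66.7%), Hox (2 and 5 of 8 genes), segmentation (18.5% and 55.6%) and neurogenesis (5 and 14 of 35 genes). A summit between neighbouring genes counted for each of them, so a bound gene is not always the only gene at its peak. Genes that share a summit are not independent, so the p values may overstate the evidence, also those for tRNA genes. How many tRNA genes share a summit was not tested.

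**Figure D3:**
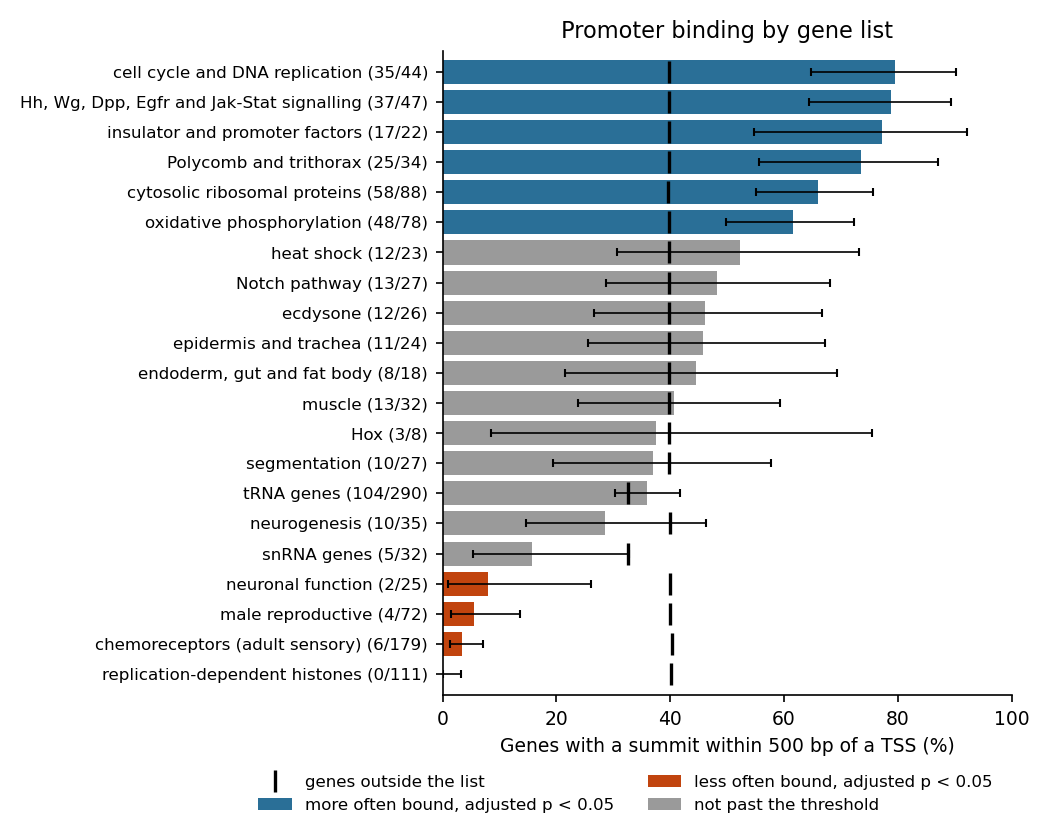
Percentage of the genes of each list with a summit within 500 bp of a TSS (x axis), with the bound and total members in parentheses, exact 95% intervals as error bars and the share of genes outside the list as a black tick. Cell cycle and DNA replication genes reached 79.5%, and chemoreceptors 3.35%.

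The sequence at the summits was examined because no binding motif of CG13287 was assumed. The DNA replication-related element (DRE, WATCGATW), the site known to be bound by DREF, was present within 50 bp of 18.5% of summits (95% interval 17.5 to 19.5) against 1.07% of control windows, a ratio of 17.2 (exact adjusted p = 2.39e-257). The core promoter motif Ohler 7 was present in 11.8% against 3.49% (ratio 3.39, exact adjusted p = 9.07e-67) and the M1BP site in 4.58% against 0.437% (ratio 10.5, exact adjusted p = 1.21e-52). The E-box CAGCTG stood in 10.4% against 5.05% (ratio 2.05, exact adjusted p = 1.65e-27). The GAGA motif of Trl was in 15.6% against 12.4% (ratio 1.26, exact adjusted p = 1.45e-06). Its excess was absent in the replicate 1 list (ratio 1.07) and in GC-matched pairs (0.995), and turned to a deficit among the 2977 peaks with the highest signal (0.843, exact adjusted p = 0.0343). The 4 named motifs other than GAGA kept their direction and passed the threshold in both replicates' own lists, where DRE reached 24.8% of summits in replicate 1 and 15.0% in replicate 2.

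Of the 28 known motifs 7 were more frequent at summits, the remaining 2 being the CTCF core (ratio 4.08) and the forkhead motif (1.21), both short of the threshold in GC-matched pairs (1.75 and 1.13) and the latter also against windows 1000 bp away (1.12). The CTCF core ratio was 2.20 in replicate 1 and 6.69 in replicate 2. The 5 less frequent ones were those of Zelda (ratio 0.540), nuclear receptors (0.545), ETS factors (0.472), KLF/Sp factors (0.547) and Ttk (0.375). None of these 5 passed the threshold in the smaller set of 1390 GC-matched pairs, where Ttk (0.364) and nuclear receptors (0.558) kept nearly the same ratio, ETS (0.679) and Zelda (0.700) came closer to 1 and KLF/Sp was at 1.00. The missed threshold thus does not show that GC content explains all 5. Zelda also missed the threshold in the lists of replicate 1 (0.545) and replicate 2 (0.633). In those GC-matched pairs DRE, Ohler 7, M1BP and the E-box CAGCTG were more frequent, and the Cad/Abd-B motif was less frequent (ratio 0.596, exact adjusted p = 1.17e-04). These 8 motifs outside the naming rule were named after their values had been seen.

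Among all 6-mers TATCGA had the smallest p, and stood in 27.6% of summit windows (95% interval 26.5 to 28.8) against 3.46% of control windows (ratio 7.99, p at its floor of 1e-300). It stood in 22.9% of replicate 2 summits and 35.9% of replicate 1 summits. The next by p were ATCGAT (24.1% against 3.24%), CGATAG (20.8% against 2.45%, with a higher ratio of 8.49), CGATAA (17.9% against 4.21%), ATATCG (14.9% against 3.80%) and ACTATC (11.4% against 2.60%). Then came CGATAC (9.14% against 2.05%), AATCGA (16.0% against 6.58%), GCGATA (10.6% against 3.34%) and GATAGC (8.70% against 2.52%). Several of these overlap one another, so they are not independent counts. In all, 399 6-mers were more and 617 less frequent at summits, and in GC-matched pairs, which left 1390 peaks, these were 101 and 134.

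TATCGA followed the signal of the peaks. Of the 596 summits with the highest signal 62.9% carried it (95% interval 58.9 to 66.8), and of the 595 with the lowest 7.39% did (5.42 to 9.80). Of the 20 peaks named above 17 carried it, the exceptions being Jwa, PGAP3 and Ube3a. It stood at 30.1% of promoter summits and 11.4% of other summits. DRE fell from 45.1% to 3.53% and Ohler 7 from 21.3% to 4.20% between the same groups, while the E-box CAGCTG gave 5.37% and 8.24%, with a highest value of 14.4% in the fourth of the 10 groups by signal. The M1BP site gave 3.86% and 1.68%, with a highest value of 5.71% in groups 6 and 7. TATCGA sites were densest at the summit itself, with 5.28 sites per kb within 50 bp and 0.445 at 450 to 500 bp. The groups by signal include 787 weaker summits of overlapping pairs of peaks, of which 11.1% had TATCGA within 50 bp. How much these weaker summits add to the trend with signal was not tested.

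**Figure D4:**
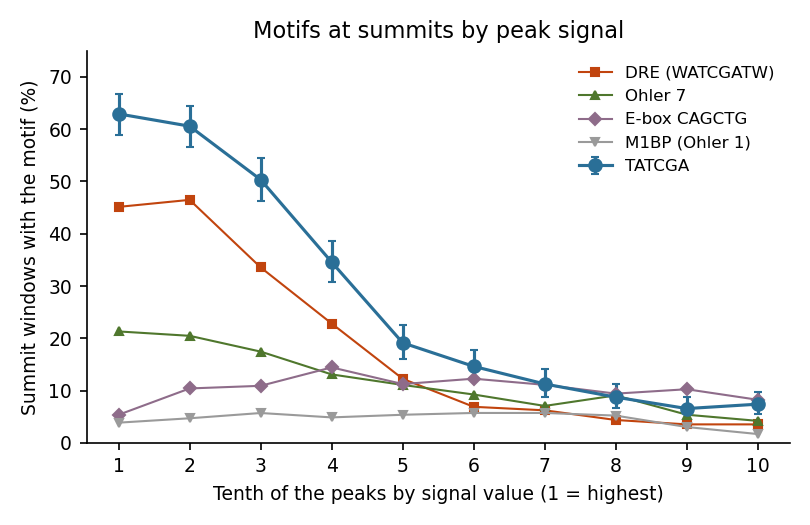
Percentage of summit windows with each motif (y axis) in 10 groups of 595 or 596 peaks by signal value (x axis, 1 the highest), with exact 95% intervals for TATCGA. TATCGA fell from 62.9% to 7.39%.

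**Figure D5:**
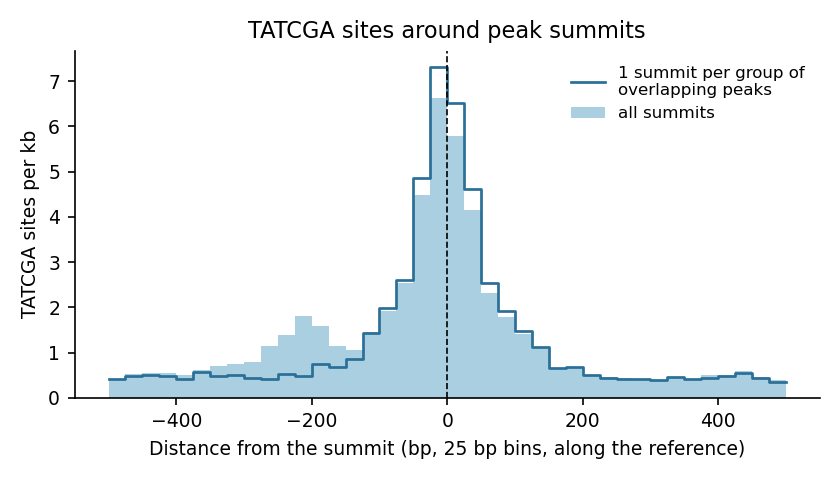
TATCGA sites per kb (y axis) by distance from the summit in bp along the reference (x axis, 25 bp bins), for all summits (bars) and for 1 summit per group of overlapping peaks (line). The density within 50 bp of all summits was 5.28 sites per kb, and a lesser rise near -200 bp is seen in the bars only.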

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

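The comparisons with unbound promoters, with GC-matched windows and with ribosomal protein genes, and that of replicate 2 peaks with the ranked list of replicate 1, were set out before their results were seen. The comparison of promoter shares, that of ribosomal protein with other promoters lacking TATCGA, and the placements of replicate 2 peaks against the ranked list that kept the promoter share were chosen afterwards.

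Peaks on the mitochondrial genome lay outside the comparisons and are noted because they appeared in some lists and not in others. The filtered and the ranked list of replicate 1 each held 17 such peaks, the optimal list held 5, and both lists of replicate 2 held 0. In replicate 1 they covered 47.6% of the 19524 bp and reached a signal of 20125, against 1503 for the highest nuclear peak. In the optimal list the highest reached 19876. No explanation was tested for these peaks.

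TATCGA stood at 30.1% of promoter summits, and 3 technical explanations were weighed. Position and base composition common to promoters are argued against, because this share was 6.023 times that of windows at the same distances from the TSSs of 3199 unbound genes, and GC content by a ratio of 9.17 in GC-matched pairs. Signal that rises at any highly transcribed gene would put ribosomal protein promoters without TATCGA above other promoters with it, and the difference was instead -0.9997 in log2 (medians 203 over 46 summits and 406 over 1528, two-sided permutation p = 1e-05, the smallest possible). Among promoters without TATCGA, those of ribosomal protein genes lay 0.38 in log2 above the 3559 others (medians 203 and 156, permutation p = 0.01), so a contribution of transcription to signal remains open. Also open is whether the tagged protein or a partner contacts the sequence, and no biological explanation was tested because the series has 1 group.

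Replicate 2 gave 1.84 times as many peaks as replicate 1. Of the 3524 replicate 2 peaks without a filtered partner, 81.78% overlapped a peak of the ranked list of replicate 1, against an average of 14.3% and at most 15.9% in random placements, or 34.1% and at most 37.1% where these kept the promoter share. This is consistent with regions shared by both libraries that fell below the filter in replicate 1. The promoter share of these peaks was 69.24%, against 91.8% of peaks with a partner, a value between the bounds set for the same and for a different kind of region, so a difference in kind cannot be told apart from weaker peaks of the same kind. Library depth, which could also differ, is unknown, and no biological difference between the replicates is given in the labels.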

How the results depend on the processing

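The alternatives with 1 summit per group of overlapping peaks, canonical TSSs only or unbound promoters, and those for head-to-head genes, summit position and signal groups, were chosen after seeing the data; all others were planned. Of 638 alternative values, 541 kept their side of the threshold or, where untested, stayed near the main value by a fixed rule. Another 60 moved, 23 lost and 8 gained the threshold, and 6 changed direction with a value past the threshold (reversed). The 60 include the signals of the 20 named peaks in each replicate's own list, where any difference from the conservative list counted as moved. The cause was not tested except where stated. Depth is unknown, so its limits could not be set.

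The peaks above the median signal are fewer by construction: 2977 (conservative), 3515 (optimal), 2007 (replicate 1) and 3670 (replicate 2), and 3699 bound genes. There signalling genes were bound at 40.43% and oxidative phosphorylation genes at 37.18%, 8 motifs were less frequent, the GAGA ratio reversed to 0.8434 and the TATA box passed at 1.776. The optimal list took tRNA genes to 44.48% (past the threshold), Zelda to 0.6038 (lost) and the initiator to 1.107 (past). Promoters of 1000 bp took tRNA genes to 43.10% (past), promoters of 200 bp the 5' untranslated regions to 0.9632 (lost), and gene bodies neuronal function to 28.00% (lost). The rank correlation was 0.8947 for summits within 100 bp and 0.8466 in ranked lists.

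GC-matched pairs were fewer (1390 of 5955). They gave 101 more and 134 less frequent 6-mers, 4 more frequent motifs and 1 less frequent (Cad/Abd-B, not among the 5 of all pairs). GAGA (0.9947, just below 1), KLF/Sp (1.000, no difference), Zelda (0.7000), CTCF core (1.750), forkhead (1.133), nuclear receptor (0.5581), ETS (0.6786) and Ttk (0.3636) missed the threshold. Unbound promoters reversed the TATA box (0.4045) and initiator (0.6585), took KLF/Sp to 1.043 (not past the threshold) and lost Zelda (0.6389) and the nuclear receptor motif (0.7245). With 1 summit per group, 3 motifs were less frequent and Zelda (0.7586) and KLF/Sp (0.5918) were lost. Windows of 25 bp also left 3, losing Zelda (0.4286) and KLF/Sp (0.5556). Control windows 1000 bp away lost Zelda (0.6136) and forkhead (1.118).

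In the 2 single-replicate lists, values ranged from 0.9316 to 1.011 for arm 3L, from 18.97 to 52.07% for tRNA genes (reversed in replicate 1), from 7 to 11 for motifs more frequent, from 1.069 to 1.398 for GAGA, from 0.5455 to 0.6327 for Zelda, from 1.108 to 1.457 for the TATA box and from 1.061 to 1.089 for the initiator. Over all settings the ratio ranged from 10.6 to 26.5 for DRE, from 8.75 to 27.3 for the M1BP site and from 6.02 to 14.6 for TATCGA, and the odds ratio from 1.89 to 9.06 for signalling and from 3.67 to 8.41 for cell cycle genes. No paired analysis was possible because the series has 1 group.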

Other observations

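The comparisons of head-to-head genes, of core promoter motifs against unbound promoters, of CGATA copies and of overlapping peaks were all chosen after the data had been seen.

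Head-to-head genes, whose start sites lie at most 1000 bp apart on opposite strands, were bound more often than other genes. Of 2183 different genes, taken as 1 from each of 2204 such pairs, 63.3% were bound (95% interval 61.2 to 65.3), against 24.9% (24.1 to 25.8) of 9630 genes in no such pair. The odds ratio was 5.20 (two-sided Fisher's exact p = 1.73e-247), and median signals were 299 and 211. A summit between both genes counts for either, which raises the share for pairs by construction to an extent not tested. Promoter summits also carried the TATA box less often than windows at unbound promoters, 4.52% against 11.2% (ratio 0.404), and the initiator motif less often, 21.4% against 32.5% (ratio 0.659). Against windows 500 bp away neither motif passed the threshold (ratios 1.17 and 1.06), but the TATA box was more frequent at the 2977 peaks with the highest signal (1.78) and in replicate 1 (1.46), and the initiator in the optimal list (1.11) and in replicate 2 (1.09). The direction for both motifs thus depends on the control.

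Peak signal rose with the number of CGATA copies at promoter summits without the DRE (WATCGATW). Median signals were 148 over 2948 summits with none, 207 over 717 with 1 copy, 367 over 310 with 2 copies and 418 over 139 with 3 or more. Weaker summits of overlapping pairs, described below, were included. Whether they lower the medians of the groups with few copies was not tested. Summits with 2 or more copies exceeded those with none by 1.33 in log2 (two-sided permutation p = 1e-05, the smallest possible). When only TATCGATA was left out, 389 of 4503 summits still carried another form of the DRE, and the difference was 1.523 (two-sided permutation p = 1e-05). Clustered CGATA is known as the site of the insulator protein BEAF-32, and DREF binds the DRE. A hypothesis is that the signal may follow CGATA copies even without a full match to the DRE. CGATA is itself part of TATCGATA, so sites close to the DRE may remain among the summits without WATCGATW. The comparison therefore cannot tell CGATA copies from incomplete DRE sites. With TATCGATA the medians were 350 over 207 summits with 2 copies and 511 over 449 with 3 or more. Without TATCGATA they were close to these, at 377 over 458 summits and 508 over 231. Differences between summits with and without TATCGATA were not tested. All summits with TATCGATA had 2 or more copies, because this palindrome holds CGATA on both strands. Neither protein was measured here, and copies of CGATA were counted on the same peaks in which the pattern was noticed.

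Overlapping peaks showed an arrangement that follows the reference coordinates. In 773 of 799 overlapping pairs of the conservative list (96.7%, 95% interval 95.3 to 97.9) the weaker summit lay at the higher coordinate, at a median distance of 203 bp, with a median signal 0.260 of that of the stronger. A second position set by the direction of the gene would reverse between strands, but the shares near genes on the plus and minus strands differed by 0.1997 percentage points, the lower being 96.65%. Of the 787 weaker summits 35.8% had TATCGA 150 to 250 bp towards lower coordinates, 11.1% had it within 50 bp and 3.68% had it 150 to 250 bp towards higher ones. In 88.7% of pairs the weaker summit lay 150 to 250 bp above the stronger, so the 35.8% largely counts sites at the stronger summit. Other summits had TATCGA within 50 bp in 30.7% of cases, so the 35.8% cannot tell a displaced summit from a second binding position. The common direction along the reference, on either gene strand, goes with a displaced second summit from peak calling or read placement. That hypothesis was formed and tested on the same lists. The lists of replicate 1 and replicate 2 gave 96.4% and 94.4%, and 13.2% of the summits of the conservative list were such weaker summits.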
